A study of Mus musculus with 11 samples.

How the data were processed

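RNA from FACS-sorted mouse lung adenocarcinoma cells was profiled on 11 Agilent whole-genome mouse arrays. The tumours carried an activated Kras allele and a floxed Trp53 allele, and the labels place 6 arrays in the TPC group and 5 in the non-TPC group. TPC cells were sorted as positive for CD24 and ITGB4 with high Notch, and non-TPC cells were the other tumour cells. The labels do not say which Notch receptor was stained and do not spell out TPC. The design text speaks of 6 mice, and it does not tie arrays to mice. Total RNA went through a pair of amplification rounds before labelling with Cy5, per the labels' protocols. Amplification of small amounts can distort the level of single transcripts, and no measure of it was used here.

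The deposited scanner files hold spot intensity on a linear scale in 2 colour channels, per the file headers, which name Agilent Feature Extraction 11.0.1.1 and a 2-colour protocol. The submitters' processing notes name Agilent Feature Extraction 9.5, so the version is not settled. The labels describe the Cy5 (red) sample only. The content of the green channel is not given in the sources used here, and its spot signals had a Spearman correlation of 0.968 to 0.985 between arrays. The deposited log ratio column is log10 of red over green, per the file headers. The authors' series matrix holds log2 of red over green: each column had a slope of 1.00 on that array's log ratio after conversion from log10 to log2, with r from 0.994 to 1.000. That table was not centred per gene. Its medians were -0.20, 0.04, -0.07, -0.16, -0.17 and -0.10 in TPC replicates 1 to 6 and -0.11, 0.12, -0.06, 0.04 and -0.05 in non-TPC replicates 1 to 5.

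All computed values started from the red median spot signal. The planned design had named the mean signal, which the files used here lack. Red signal was corrected for the local background median with normexp at offset 50, quantile normalized between arrays and log2 transformed in limma 3.58.1 under R 4.3.3. The 1639 control spots and spots marked as red outliers were left out, and the spots of a probe were averaged. Quantile normalization gives the brightest probe of every array the same value. Probes well above background on at least 5 arrays were kept. Each gene was represented by its probe of highest mean signal. Of 41174 probes, 22951 matched a symbol through their transcript accession in a RefSeq table of assembly GRCm38.p6, and 18223 kept the accession as their name. The array's annotation names another build, so no coordinates are given. The test covered 24264 features, 14094 of them with a symbol. Probes of closely related genes, such as the H2 family, can bind each other's transcripts, and such genes are uncertain. Among called features, 115 had several kept probes and 19 of these had probes that differed in sign.

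Groups were compared with limma's linear model and empirical Bayes test, two-sided, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. Array number limits the precision: p-values measure the spread between these samples, and no label says that each came from a separate mouse. Gene lists were fixed before the data were examined, as were the groups, the test and the alternatives, apart from those named as added. Of 39 lists, the sort antigens and the genotype genes served as checks, and 37 lists of cell type markers and pathways were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation beside it. Fry tested whether a list's genes moved on balance one way. Named genes are the 12 largest rises and the 12 largest falls past the threshold among genes with a symbol, the 4 members of smallest p in each list, all sort antigens and both genotype genes. Clone-type names (Rik, Gm, LOC) were passed over.

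Replicate numbers were checked for pairing. Deviations from the group means of same-numbered arrays had correlations of 0.54, 0.48, 0.31, 0.53 and 0.39 for replicates 1 to 5, all over 0.1, so the numbers were taken to pair the samples. Replicate 5 had a higher correlation, 0.42, with an array of another number. TPC replicate 6 has no partner. The header barcodes put the arrays on 4 slides. Slide 1 held TPC replicate 1 and non-TPC replicates 1 and 2, slide 2 held TPC replicate 3 and non-TPC replicates 3 and 4, and slide 3 held TPC replicate 6 and non-TPC replicate 5. Slide 4 held TPC replicates 2, 4 and 5 and was also the only slide of the second scan session. Values with slide as a fixed block (the slide block) are given for the counts and for each list past the threshold. For the lists, medians within slides 1 to 3 are given too, and for the named genes a count and a range. The arrays of slide 3 differ in replicate number, so its medians are not those of a pair.

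On simulated data for the comparison of TPC with non-TPC, drawn from the real means and spreads of 24212 features, limma recovered 66 of 100 genes changed by 1 on the log2 scale and 98 of 100 changed by 2. It called 170 genes, 6 of them unchanged, and camera called only the list that had been shifted. The simulated noise was independent between genes and held no pairing or slide effect. It therefore cannot show how often camera calls an unshifted list whose genes move together. Alternatives covered the scaling, the signal column, the colour channel, the authors' values, background correction, the filter on dim probes, several probes per gene, the variance prior, array weights, slide, pairing and each array left out in turn. After the data were seen, a ratio with the replicate block, the external control level as a covariate and a comparison without pair 5 were added.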

Results

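Gene expression was measured in tumour cells sorted from primary mouse lung adenocarcinomas driven by mutant Kras with Trp53 deletion alleles, to ask how TPC cells (CD24 and ITGB4 positive, Notch high) differ from the remaining tumour cells. There were 6 TPC and 5 non-TPC arrays. The share of red spots well above background was 68.8% ± 4.5 (SD, n = 6) on TPC arrays and 77.5% ± 5.9 (SD, n = 5) on non-TPC arrays (exact permutation p = 0.026, two-sided, 0.078 after Benjamini-Hochberg adjustment over 6 array measures). Median red spot signal ran from 133 to 270. Its mean was 175 on TPC and 217 on non-TPC arrays (exact permutation p = 0.095, adjusted 0.14). The TPC array was higher in 0 of 5 pairs. The level of synthetic external control transcripts relative to the sample's own RNA differed by 2.05 on the log2 scale between TPC and non-TPC arrays (exact permutation p = 0.0087, adjusted 0.052), with the TPC array higher in 4 of 5 pairs of arrays with the same replicate number.

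The sort antigens were examined first as a check of the labels. The sort was on protein antigens, while the arrays measure transcripts, so this check is indirect. Itgb4, which encodes the integrin subunit used for sorting, had a normalized log2 intensity of 12.65 ± 0.58 (SD, n = 6) in TPC and 11.63 ± 0.31 (SD, n = 5) in non-TPC. Its difference of 1.02 ± 0.26 (SE), higher in 5 of 5 pairs, did not pass over all genes (limma adjusted p = 0.066), passed when adjusted over the list alone, and passed with the replicate block (adjusted p = 0.013). Notch3 differed by 0.83 ± 0.40 (SE, adjusted p = 0.29) and was higher in 4 of 5 pairs. Cd24a differed by -0.22 ± 0.22 (SE, adjusted p = 0.63), Notch1 by 0.22 ± 0.28, Notch2 by -0.15 ± 0.19 and Notch4 by -0.25 ± 0.16. None of the 6 genes passed over all genes in the unblocked test. Among the genotype genes, Kras differed by -0.20 ± 0.18 (SE, adjusted p = 0.61) and Trp53 by 0.03 ± 0.12 (adjusted p = 0.93).

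**Figure D1:**
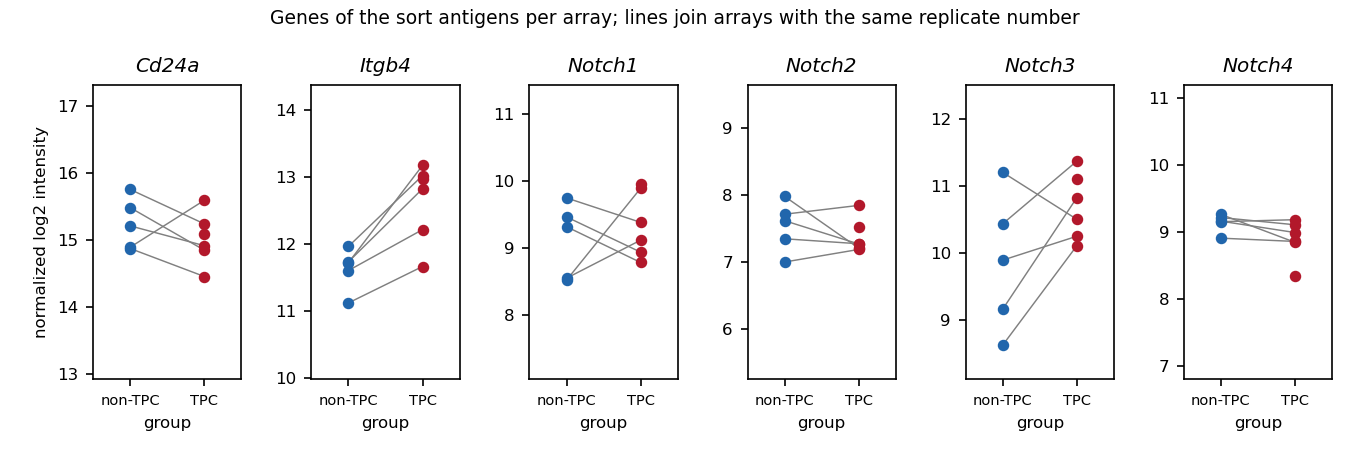
Normalized log2 intensity of the 6 sort antigen genes on each array, with non-TPC arrays at left and TPC arrays at right of each panel and grey lines joining arrays with the same replicate number. Itgb4 was higher in TPC in 5 of 5 pairs and Notch3 in 4 of 5.

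TPC cells had higher transcript levels of 256 features and lower levels of 197 than non-TPC cells, and 108 and 92 of these differed at least 2-fold. The largest rise was in Abcg1, a cholesterol and phospholipid exporter, which was 3.79-fold higher in TPC (log2 difference 1.92 ± 0.30 SE, adjusted p = 0.011). Tph1, the enzyme that starts serotonin synthesis outside neurons, was 3.45-fold higher, and the extracellular proteoglycan gene Spock2 was 3.38-fold higher. Tshb, the beta subunit of thyrotropin, rose 2.92-fold, and Tenm4, a teneurin adhesion protein, rose 2.92-fold. The matrix metalloproteinase gene Mmp3 rose 2.89-fold, the Rho exchange factor gene Plekhg3 rose 2.88-fold and the small GTPase gene Rhoc rose 2.78-fold. The semaphorin gene Sema7a had the smallest spread of these genes, with 12.85 ± 0.16 (SD, n = 6) in TPC and 11.41 ± 0.17 (SD, n = 5) in non-TPC (2.72-fold, limma adjusted p = 0.0014). Padi2, a protein-citrullinating enzyme, rose 2.73-fold, the phosphatase regulatory subunit gene Ppp2r2c rose 2.71-fold, and Fcmr, the IgM Fc receptor, rose 2.70-fold. All 12 of these genes were higher in 5 of 5 pairs. A second Spock2 probe of nearly equal signal went the other way (log2 difference -0.44), so the rise of that gene rests on a single probe, and the mean of its probes differed by 0.66 (adjusted p = 0.079). In the authors' deposited red over green ratios Tshb, Tph1 and Fcmr differed by 0.29, 0.63 and 0.47, which did not pass (adjusted p from 0.24 to 0.58). The size of some rises depended on the processing. Over the alternatives the log2 difference of Tph1 ran from 0.63 to 2.66. That of Ppp2r2c, whose non-TPC mean was low (6.98), ran from 0.995 to 2.38.

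The largest fall was in Fgg, which encodes the fibrinogen gamma chain. It was 6.32-fold lower in TPC, at 11.50 ± 0.59 (SD, n = 6) against 14.16 ± 1.37 (SD, n = 5), with an adjusted p of 0.029 in limma. Itih4, another gene of secreted acute-phase proteins, was 4.67-fold lower. The amino acid transporter gene Slc6a20a was 5.33-fold lower, the lysophospholipid transporter gene Mfsd2a 4.98-fold lower and the sodium and glucose cotransporter gene Slc5a1 2.96-fold lower. Mid1ip1, an activator of fatty acid synthesis, was 3.30-fold lower and the acyl-CoA oxidase-like gene Acoxl 3.09-fold lower. Ehd3, an endosomal recycling protein, was 4.24-fold lower, Itm2a was 3.74-fold lower, and the histamine-inactivating enzyme gene Hnmt was 2.92-fold lower. The ETS transcription factor gene Etv5 was 3.18-fold lower by its brighter probe (log2 difference -1.67), while its second probe gave -0.22. H2-Bl, a class I histocompatibility gene, was 3.26-fold lower, but its 2 dimmer probes gave 0.25 and 0.19, and related H2 genes may be read by the same probe. All 12 genes were lower in 5 of 5 pairs. In the authors' deposited red over green ratios, Fgg, Acoxl, Slc5a1 and Hnmt had differences of 0.22, 0.07, 0.08 and 0.27, Slc6a20a one of -0.17 and Itih4 one of -0.47, and none of the 6 passed (adjusted p from 0.29 to 0.90). In computed ratios Fgg and Slc6a20a passed, with -1.57 and -1.52, and Itih4 (-0.73), Acoxl (-0.34), Slc5a1 (-0.88) and Hnmt (-0.19) did not. H2-Bl differed by -0.42 (adjusted p = 0.30) with the mean of its probes.

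**Figure D2:**
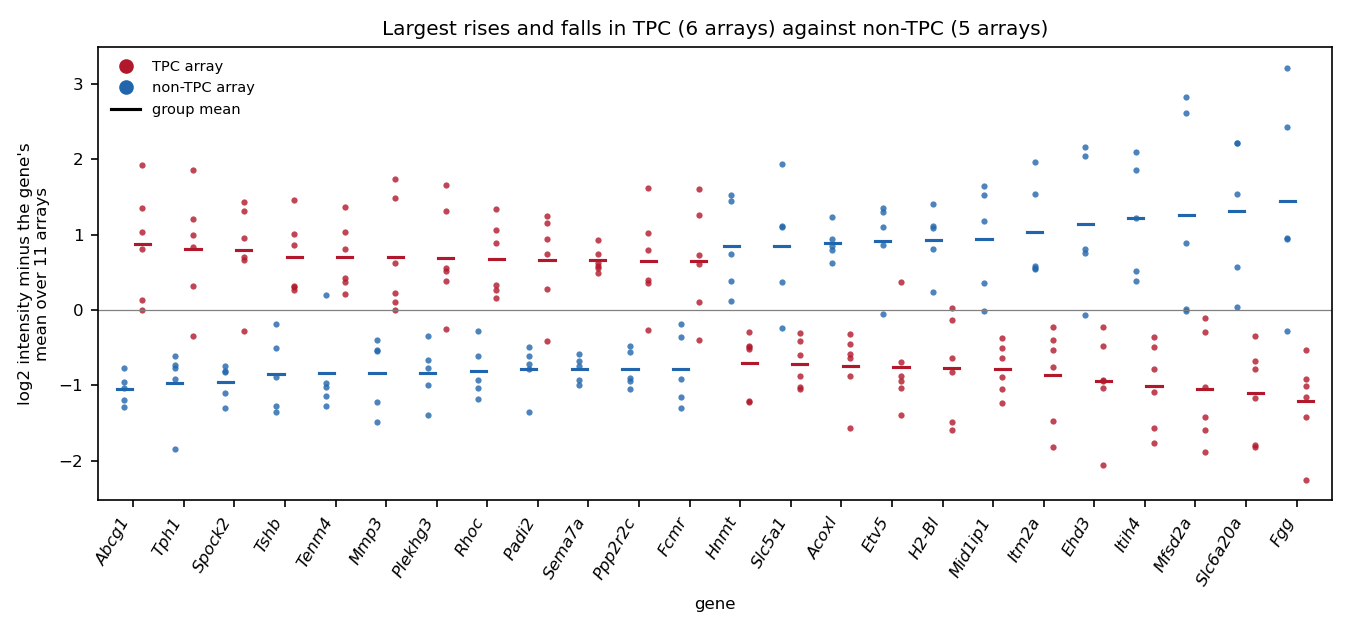
Log2 intensity of the 12 genes with the largest rises and the 12 with the largest falls in TPC, drawn as each array's value minus the gene's mean over all 11 arrays; points are arrays and short bars are group means (6 TPC, 5 non-TPC). Abcg1 shows the largest rise (log2 difference 1.92) and Fgg the largest fall (-2.66).

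With the replicate block, which uses the pairing, limma called 894 features higher and 581 lower in TPC, and 445 of the 453 unblocked calls kept their direction and passed again. With slide as a fixed block, 7 passed as higher and 3 as lower, all 10 with the same direction as without the block. Among them were Sema7a, Tshb and Ehd3, while 3587 features had an unadjusted p below 0.05. Slide 4 held TPC arrays alone, so in this fit the group difference rested on slides 1 to 3. The differences of the 453 unblocked calls did not shrink with the slide block, with a median in their own direction of 0.98 against 0.96 and all 453 of the same sign, while their median SE went from 0.19 to 0.22. These features had been chosen for their differences on the same arrays, so this similarity was favoured in advance. Of the 43 called genes named by rule, 4 passed with the slide block, Sema7a, Tshb, Ehd3 and Cyp2s1. The other 39 did not (limma adjusted p from 0.051 to 0.21). With slide as a random block, limma called 275 features higher and 225 lower, of which 244 and 188 were unblocked calls. Of the 43 named genes, 42 passed in that fit. A random block also uses comparisons between slides, so it does not fully remove a difference between them. In computed ratios 29 of the 43 passed, and in the authors' deposited ratios 8. Without the slide that held TPC arrays alone, 2 passed as higher and 0 as lower, with 3209 at an unadjusted p below 0.05. Like the fixed slide block, that fit compares the groups on slides 1 to 3 with fewer TPC arrays, so it is not a separate check. Scaling to the 75th percentile, which moved the median of all features from 0.01 to 0.11, gave 258 higher and 113 lower. The processed red signal gave 63 and 34, the authors' deposited ratios 47 and 41, and a normexp offset of 16 gave 151 and 109. Computed ratios gave 314 and 178, of which 215 and 116 were also called in the main fit. Keeping only probes above background on all arrays gave 316 and 251. The counts moved with single arrays. Leaving out TPC replicate 1, 2, 3, 4 or 6 left 97, 55, 132, 93 or 67 features higher and 59, 29, 95, 60 or 38 lower. Without TPC replicate 5 there were 623 higher and 553 lower. Leaving out non-TPC replicate 1, 2, 3, 4 or 5 left 91, 101, 127, 88 or 157 higher and 37, 77, 127, 84 or 107 lower. With the external control level as a covariate, limma called 0 features either way, with 1433 at an unadjusted p below 0.05.

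Alveolar type 2 genes, the markers of the surfactant-producing cells of the alveolus, were lower in TPC. Of 20 measured, 6 fell, 0 rose and 14 did not pass over all genes. Adjusted over the list alone, 15 fell. Slc34a2, the phosphate transporter of type 2 cells, was 2.54-fold lower (adjusted p = 0.019), Lpcat1, which makes surfactant phosphatidylcholine, was 2.30-fold lower (adjusted p = 0.025), and the fatty acid desaturase gene Scd1 was 2.43-fold lower (adjusted p = 0.029), with Etv5 as above. In red over green ratios Slc34a2 differed by 0.08 (adjusted p = 0.77), and in the authors' deposited ratios by 0.57 (adjusted p = 0.093). The list's median log2 difference was -0.71 (camera adjusted p = 1.07e-10, and adjusted p = 0.040 with an estimated correlation). Within slides 1, 2 and 3 the median was -1.14, -0.38 and -0.88, and camera with the slide block gave an adjusted p of 9.09e-12. With an estimated correlation and the replicate block together, the adjusted p was 0.26. Of the 32 groupings of the arrays that part all 5 pairs, 2 gave the list a camera p as small in either direction, the real one included. The 32 include the real contrast nearly reversed, so 2 is about the lowest count a real difference could give. Sftpc, the surfactant protein C gene, was the brightest probe on all 11 arrays, so quantile normalization fixed its value. With 75th percentile scaling Sftpc differed by 0.52 ± 0.26 (SE, adjusted p = 0.31), Sftpa1 by 0.31 ± 0.25 (0.54), Sftpb by -0.52 ± 0.22 (0.22) and Sftpd by -0.45 ± 0.32 (0.49). Club cell genes were also lower as a list (median -0.33, camera adjusted p = 0.026, and adjusted p = 0.53 with an estimated correlation). Of 16 club genes, 2 fell, the aldehyde dehydrogenase gene Aldh1a7 by 2.05-fold and the carboxylesterase gene Ces1d by 1.77-fold. In red over green ratios both were small and did not pass, with -0.18 for Aldh1a7 (adjusted p = 0.42) and -0.18 for Ces1d (0.60), and -0.14 and -0.09 in the authors' deposited ratios. For the list club, the median within slides 1, 2 and 3 was -1.15, 0.09 and -0.53 (slide-block adjusted p = 0.0029), and the list did not pass without TPC replicate 1 (adjusted p = 0.10), non-TPC replicate 1 (0.070) or non-TPC replicate 4 (0.0505), nor with 75th percentile scaling (0.052) or the processed red signal (0.18).

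Among the other epithelial lists, alveolar type 1 and gut-type epithelium passed camera as higher in TPC, and neither passed with an estimated correlation. In the alveolar type 1 list, which marks the flat gas-exchange cells, 1 of 13 measured genes rose, Pxdc1 (2.41-fold, adjusted p = 0.032), and 3 rose when adjusted over the list alone. The list's median was 0.58 (camera adjusted p = 0.0022, and adjusted p = 0.22 with an estimated correlation), with 0.49, 0.34 and 0.74 within slides 1, 2 and 3 and a slide-block adjusted p of 0.0025. In the gut-type epithelium list, 2 of 18 genes rose. These were Onecut2, a transcription factor gene (2.60-fold, adjusted p = 0.011), and Anxa10, an annexin of gastric epithelium (2.31-fold, adjusted p = 0.042). In the same list Pigr, the transporter of mucosal antibodies, fell (2.03-fold, adjusted p = 0.046). It was above background on only 4 of 6 TPC arrays, so the size of its fall is uncertain. Over the alternatives its log2 difference ran from -2.26 to -0.50. In the authors' deposited ratios Anxa10 differed by 0.0068 (adjusted p = 0.996), and in computed ratios Pigr differed by -0.50 (adjusted p = 0.13). Adjusted over the list alone, 7 rose and 1 fell. The gut-type median was 0.44 (camera adjusted p = 0.0022, and adjusted p = 0.066 with an estimated correlation). It was 0.29, 0.52 and 0.69 within slides 1, 2 and 3, the slide-block adjusted p was 0.0025, and the list did not pass in the authors' deposited ratios (adjusted p = 0.42).

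**Figure D3:**
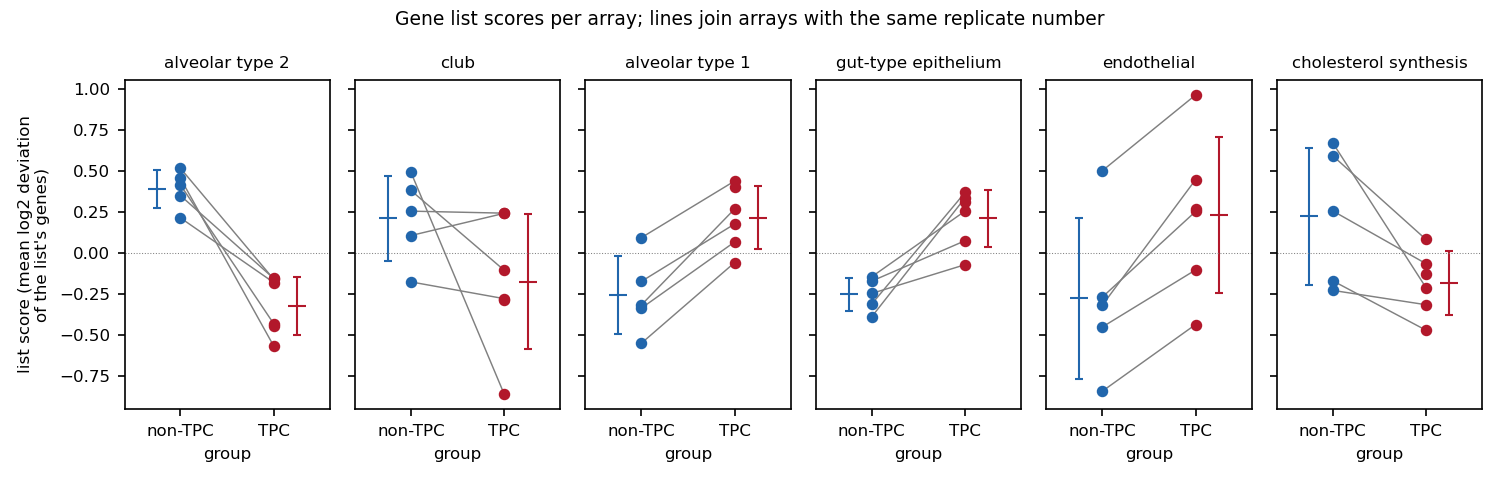
List scores on each array for 6 gene lists, each the mean over the list's genes of the log2 deviation from the gene's mean over all arrays; points are arrays, grey lines join arrays with the same replicate number, and bars at the side give mean and SD (6 TPC, 5 non-TPC). The alveolar type 2 scores of all TPC arrays lie below those of all non-TPC arrays, while the endothelial scores of the groups overlap.

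The other lists past the threshold held few called genes. Endothelial genes had a median of 0.42 (camera adjusted p = 0.013, and adjusted p = 0.68 with an estimated correlation), and 0 of 19 passed over all genes, 2 over the list alone and 7 with the replicate block. Ramp2, a receptor-modifying protein of vessels, differed by 1.52 ± 0.43 (SE, adjusted p = 0.084, 0.0047 with the replicate block), and Vwf, the von Willebrand factor gene, by 1.09 ± 0.36 (adjusted p = 0.13, 0.0081 with the block). Esam, an endothelial adhesion gene, went the other way, by -0.53 ± 0.22 (SE, adjusted p = 0.22, 0.073 with the block), with 0 of 5 pairs higher in TPC, and 4 of the 19 members were below 0. The endothelial median within slides 1, 2 and 3 was 0.12, 0.12 and -0.30. In pairs 1 to 5 it was 0.42, 0.52, 0.22, 0.73 and 0.45. With the replicate block the list had a camera adjusted p of 7.1e-05, and of 0.26 with an estimated correlation as well. It did not pass with the slide block (camera adjusted p = 0.93) or without the slide of TPC arrays alone (0.54). Nor did it pass with the external control level as a covariate (0.60), without TPC replicate 5 (0.17) or without non-TPC replicate 1 (0.078). Mesothelial genes had a median of 0.35 (camera adjusted p = 0.025, and adjusted p = 0.53 with an estimated correlation). Among 9 measured, Msln, the mesothelin gene, rose 2.41-fold (adjusted p = 0.011). The mesothelial median within the slides was 0.10, 0.45 and -0.31 (slide-block adjusted p = 0.24). In pairs 1 to 5 it was 0.69, 0.05, 0.33, 1.02 and 0.39. With the replicate block this list had a camera adjusted p of 0.0067, and of 0.40 with an estimated correlation as well. It did not pass without TPC replicate 5 (0.098), without non-TPC replicate 1 (0.10) or with the external control level as a covariate (0.17). Cholesterol synthesis genes had a median of -0.48 with 0 of 25 called (camera adjusted p = 0.0011, and adjusted p = 0.53 with an estimated correlation), and 4 fell with the replicate block, among them Sqle, the squalene epoxidase gene (block adjusted p = 0.044). The within-slide medians of that list were -0.71, -0.02 and -0.81, with a slide-block adjusted p of 2.62e-05. Cytoplasmic ribosomal protein genes had a median of 0.16 with 0 of 79 called (camera adjusted p = 0.0011, and adjusted p = 0.53 with an estimated correlation), and 0.30, 0.06 and 0.15 within the slides (slide-block adjusted p = 0.0014). That list did not pass in the authors' deposited ratios (0.077) or with the external control level as a covariate (0.19). MHC class II genes had a median of -0.34 with 0 of 9 called (camera adjusted p = 0.026, and adjusted p = 0.53 with an estimated correlation), and -0.74, -0.20 and -0.66 within the slides (slide-block adjusted p = 0.0013). That list did not pass without TPC replicate 1 (0.089) or without non-TPC replicate 2 (0.085), 4 (0.087) or 5 (0.057), nor with 75th percentile scaling (0.13), the processed red signal (0.37) or the authors' deposited ratios (0.19).

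In all, 9 of 37 lists passed camera at the preset correlation, 5 higher and 4 lower in TPC. With an estimated correlation 1 list passed, alveolar type 2, and by fry 3 passed, alveolar type 2, alveolar type 1 and gut-type epithelium. With the replicate block 11 lists passed, among them pan-leukocyte genes (adjusted p = 0.029) and MAPK feedback and output genes (adjusted p = 0.029), both higher. With the replicate block and an estimated correlation together these had an adjusted p of 0.40 and 0.32, and the smallest of any list was 0.26. Of 100 groupings of the 11 arrays into 6 and 5, the real one included, 42 gave at least as many lists past the threshold.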

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

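The tests of the external control level and of groupings that part all pairs were chosen after the result was seen. The tests of groupings drawn at random and of slides were planned.

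Limma called 256 features higher and 197 lower in TPC. In 100 groupings of the 11 arrays into 6 and 5, 1 grouping, the real one, gave a count at least as large in each direction, with 0 and 2 as the highest other counts. These groupings were a random sample that did not keep the pairing. Of the 32 groupings that part all 5 pairs, the 31 besides the real one called 0. Among these was the grouping with all 5 pairs exchanged, in which only TPC replicate 6 is out of place. A single misplaced array thus sufficed for a count of 0, so the groupings argue against chance without excluding it. A difference between slides as the whole cause is argued against by the pairs hybridised on 1 slide: of 500 genes ranked on pairs 2, 4 and 5, 80% went the same way in pair 3 and 92.8% in pair 1, against 49.6% and 58.2% between same-slide arrays of 1 group. The external control level cannot be told apart from the groups: with it as a covariate, the called genes' median log2 difference in their own direction went from 0.96 (interquartile range 0.80 to 1.18) to 0.69 (0.48 to 1.01), and all 453 kept their sign. No feature passed with this covariate. For the 453 called features the median SE rose from 0.19 to 0.30 while the differences shrank. They had been chosen on the same arrays, which favoured a shared sign. Why no feature passed was not tested further. A difference in RNA input may account for part of the counts, and a difference between the cell populations stays open beside it.

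Signals outside the main comparison stood out in 2 places. External control spots in the red channel differed by 2.05 on the log2 scale, TPC minus non-TPC, relative to each array's 75th percentile. In the green channel, whose content the labels do not give, 16 features passed limma between the groups, 11 higher and 5 lower in TPC. Of these, 14 had a red difference of the same sign and 13 also passed in red. Over all 453 features called in red, 287 had a green difference of the same sign, and 2621 green features had an unadjusted p below 0.05.

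Single arrays stood apart from their group in 12 of 354 gene groups, 5 of 74 list groups and 1 of 6 array measure groups, where chance gives about 1 in 20. Non-TPC replicate 1 stood apart 4 times and TPC replicate 1 stood apart 3 times. Median red signal was 270 in non-TPC replicate 1 and 200 to 215 in the other non-TPC arrays.

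Values of genes are normalized log2 intensities. Tph1 was 8.184 in non-TPC replicate 4 (others 9.11 to 9.42), and Tenm4 was 11.852 there (others 10.38 to 10.68). Ncam1 was 9.053 in TPC replicate 6 (others 8.30 to 8.52) and 9.001 in non-TPC replicate 5 (others 7.81 to 8.03). Cd52 was 10.928 in TPC replicate 2 (others 9.45 to 9.76), and Lyz2 was 17.853 in TPC replicate 1 (others 18.45 to 18.65). Msln was 16.592 in TPC replicate 4 (others 15.70 to 15.94), and Cdt1 was 12.775 in TPC replicate 5 (others 13.29 to 13.49). Blnk was 9.36 in non-TPC replicate 1 (others 9.65 to 9.76), and Tgfb1 was 8.778 there (others 9.03 to 9.13). Jag2 was 9.388 in non-TPC replicate 2 (others 8.94 to 9.06), and Gpx2 was 13.469 in non-TPC replicate 3 (others 14.17 to 14.24).

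List scores are mean log2 deviations from each gene's mean over all arrays. The pan-leukocyte score was 0.64 in TPC replicate 2 (others -0.10 to 0.07). The neutrophil score was -0.61 in TPC replicate 1 (others -0.09 to 0.21), and the laminin and hemidesmosome score was 0.31 there (others 0.03 to 0.12). The p53 target score was 0.10 in non-TPC replicate 5 (others -0.19 to -0.12). The mesenchymal transition score was 0.50 in non-TPC replicate 1 (others -0.39 to -0.13).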

How the results depend on the processing

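The ratio with the replicate block, the external control covariate and the comparison without pair 5 were chosen after the data were seen. Alveolar type 2, alveolar type 1 and cholesterol synthesis genes passed camera at the preset correlation in the same direction under all 29 alternatives that refit the genes, with list medians from -0.95 to -0.46, 0.26 to 0.65 and -0.68 to -0.25. With an estimated correlation their adjusted p was 0.040, 0.22 and 0.53, and by fry 0.00074, 0.024 and 0.22. The cause was not tested for any change given here unless stated.

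Features higher and lower in TPC numbered 63 and 34 with the processed red signal, 47 and 41 with the authors' deposited ratios, and 151 and 109 with a normexp offset of 16. They numbered 7 and 3 with slide as a fixed block and 275 and 225 with slide as a random block. With the replicate block there were 894 and 581, with the computed ratio 314 and 178, and with the ratio and replicate block 940 and 506. Without both arrays of pair 5 there were 481 and 495. Without the slide of TPC arrays alone, which leaves fewer samples, limma called 2 and 0, with 3209 features at an unadjusted p below 0.05. With the external control level as a covariate it called 0 and 0, with 1433. Features lower in TPC numbered 113 with 75th percentile scaling and 298 with array weights. Leaving out an array gave 55 (TPC replicate 2) to 623 (TPC replicate 5) higher and 29 to 553 lower, for the same arrays.

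Lists past the threshold numbered 14 with the mean of a gene's probes, 1 with an estimated correlation, 3 with fry, and 7 (without TPC replicate 5) to 14 (without TPC replicate 3) when an array was left out. Of the sort antigens, 0 to 1 passed when an array was left out. The gene that passed, Itgb4 (1 of 6), did so without TPC replicate 5, with array weights, with the replicate block, with the ratio and replicate block, and without pair 5.

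Some falls changed sign in red over green values. In the authors' deposited ratios the difference was 0.22 for Fgg, 0.066 for Acoxl, 0.085 for Slc5a1, 0.27 for Hnmt, 0.19 for Muc1 and 0.57 for Slc34a2. In the computed ratio it was 0.044 for Muc1 and 0.083 for Slc34a2, and with the replicate block as well 0.051 and 0.15. Green signal was quantile normalized without background correction, unlike in the ratios, so its difference only approximates what a ratio subtracts. The green difference was -0.99 for Acoxl (limma adjusted p = 0.024) and -1.17 for Slc34a2 (0.034). It did not pass for Fgg (-0.66, 0.34), Slc5a1 (-0.36, 0.26), Hnmt (-1.09, 0.12) or Muc1 (-0.85, 0.076). Mean green log2 signal was 5.39 in TPC and 6.05 in non-TPC for Fgg, and 5.32 and 5.68 for Slc5a1. These values lie below the median green spot of every array, so ratios of Fgg and Slc5a1 rest on dim green spots. The cause of the change in the authors' deposited ratios was not tested. Signal over background limits dim genes, since 64.3% to 84.1% of red spots were well above background on an array.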

Other observations

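The tests of slide, external control level and normal cells for alveolar type 2 genes, of slide and endothelial cells for endothelial genes, and of lists in groupings that part all pairs were chosen after the results were seen.

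Genes of lists that did not pass as a whole also differed between the sorted populations. Cyp2s1, a cytochrome P450 gene, was 2.61-fold higher in TPC (limma adjusted p = 0.038, and 0.040 with the slide block), the basal keratin gene Krt14 2.02-fold higher (0.043) and the epithelial integrin gene Itgb6 1.99-fold higher (0.049), each in 5 of 5 pairs. Among 30 interferon response genes 2 rose, Ifit3 (1.97-fold, adjusted p = 0.044) and Oasl1 (1.65-fold, 0.041), and 1 fell, the peptide transporter gene Tap1 (2.08-fold, 0.041). The cytokine gene Il33 was 1.88-fold lower (0.039), the catalase gene Cat 1.48-fold lower (0.046) and the mucin gene Muc1 2.07-fold lower (0.033), although Muc1 differed by 0.04 in red over green ratios. Krt14 differed by 0.47 in those ratios (adjusted p = 0.054), and Cat by -0.35 with 75th percentile scaling (adjusted p = 0.21). Calls of these genes depended on the processing. Of 29 alternatives, Krt14 and Oasl1 passed in 9, Itgb6, Il33 and Cat in 11, and Ifit3 in 12. Tap1 passed in 14, Muc1 in 15 and Cyp2s1 in 16.

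Lists that did not pass camera are given by their median log2 difference and adjusted p. Among epithelial lists these were pan-epithelial 0.20 (0.45), ciliated 0.11 (0.96), basal 0.09 (0.28) and neuroendocrine 0.06 (0.96). Among blood cell lists they were pan-leukocyte 0.26 (0.11), macrophage and monocyte 0.26 (0.28), neutrophil 0.05 (0.96), T and NK cell 0.17 (0.16), B cell 0.20 (0.072) and erythroid 0.03 (0.74). Fibroblast and smooth muscle genes had 0.20 (0.28), mesenchymal transition 0.20 (0.069) and laminin and hemidesmosome genes 0.30 (0.069). Signalling lists had 0.09 (0.45) for Notch, -0.06 (0.96) for Wnt, 0.24 (0.069) for MAPK and 0.17 (0.22) for p53 targets. Cell cycle G2/M genes had -0.14 (0.11), DNA replication 0.05 (0.96) and stem cell markers used in tumours 0.03 (0.96). Stress and metabolism lists had 0.32 (0.15) for immediate early and dissociation genes, 0.07 (0.17) for heat shock, 0.12 (0.45) for glycolysis and hypoxia, 0.19 (0.086) for oxidative phosphorylation and 0.17 (0.51) for NRF2 targets. Interferon response genes had -0.03 (0.90), chemokines and inflammatory cytokines 0.12 (0.11), and antioxidant, aldehyde and xenobiotic enzymes 0.20 (0.28). Median and mean differed in sign for neutrophil (mean -0.11), erythroid (-0.17) and Wnt genes (0.01), and camera's direction for ciliated genes was down.

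For alveolar type 2 genes, 1 of 100 groupings, the real one, gave a camera p as small (2.89e-12, next 8.90e-11). Among the 32 groupings that part all 5 pairs, 2 did (smallest other 1.24e-13). Direction was not counted there, and the 32 include the grouping with all 5 pairs exchanged, which is close to the real contrast reversed. A real difference could thus hardly give a count below 2, so this count cannot decide on chance. The camera adjusted p with the replicate block and an estimated correlation was 0.26, so that fit, which keeps the pairing, did not exclude chance. Slides as the whole cause are argued against by within-slide medians of -0.38 or lower. With the external control level as a covariate the median was -0.95. That level ran from 4.09 to 6.41 on TPC arrays and from 2.26 to 4.36 on non-TPC arrays. It nearly separates the groups, so this fit cannot decide on it. Normal alveolar type 2 cells in the non-TPC sort cannot be told apart from a difference within the tumour cells: the median of club genes was above 0 in 2 of the 5 pairs, and that of alveolar type 2 genes was below 0 in all 5. With 75th percentile scaling the surfactant genes Sftpc and Sftpa1 differed by 0.52 ± 0.26 (SE) and 0.31 ± 0.25, in sign against the explanation. Sftpb and Sftpd differed by -0.52 ± 0.22 and -0.45 ± 0.32, in sign with it. None of these surfactant genes passed (limma adjusted p from 0.22 to 0.54). That scaling also moved the median of all features from 0.01 to 0.11, so these genes decide neither way. A difference between the sorted tumour cell populations, which the design names, stays open as untested.

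For endothelial genes, 47 of 100 groupings gave a camera p as small (0.0021, smallest other 1.04e-14). Groupings with far smaller p point to a structure among the arrays, and these groupings were drawn without keeping the pairing. Among the 32 groupings that part all pairs, 3 gave a camera p as small (smallest other 0.00079). A count of about 2 is the lowest there, as above, so these groupings could not exclude chance. Slide cannot be told apart, since only 2 pairs share a slide, with a median of 0.22 in the lower. Over all arrays of slides 1, 2 and 3 the within-slide median was 0.12, 0.12 and -0.30. Slide 3 held no pair, so its value does not compare arrays of the same replicate number. In all 5 pairs the median was above 0, from 0.22 to 0.73, but in pairs 2, 4 and 5 the TPC array lay on slide 4. Endothelial cells in the TPC sort cannot be told apart either: the average estimated correlation between members over arrays was 0.52, but the list did not pass with the slide block (adjusted p = 0.93) and 4 of 19 members were below 0, Esam among them (-0.53). The labels name a gate on CD24, ITGB4 and Notch and no step that removes endothelial cells. The number of lists past the threshold, 9, was reached by 42 of 100 groupings (highest other 15), so chance cannot be excluded for it.

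Of the other lists past the threshold, a camera p as small came from 2 of 100 groupings for gut-type epithelium, 7 for alveolar type 1, 9 for ribosomal proteins, 22 for club and for MHC class II, 26 for mesothelial and 27 for cholesterol synthesis genes. Among the 32 groupings that part all 5 pairs, a camera p as small in either direction came from 2 for gut-type epithelium and for alveolar type 1. It came from 3 for endothelial and for MHC class II, 4 for ribosomal proteins, 5 for mesothelial, 12 for cholesterol synthesis and 13 for club genes. The 32 include the real contrast nearly reversed, so 2 is about the lowest count a real difference could give. In those groupings the real one called 453 features and the other 31 called 0 each.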
